A study of Mus musculus with 4 samples.

How the data were processed

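RNA sequencing libraries were made from 1 µg of total RNA with the Illumina TruSeq RNA kit, per the labels' protocols, from Setd2 fl/fl mouse bone marrow stromal cells that had received a GFP or a Cre lentivirus. The kit keeps no strand information. The deposited table holds whole-number read counts for 44788 genes in 4 libraries, 2 per virus, with no normalization. Reads were aligned with HISAT2 to GRCm38, per the submitters' processing notes. The aligner version, the counting program, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes are therefore uncertain. Of 114 named genes, 113 were found in GENCODE M21, and 35 share exon bases with another gene of that annotation. Beside those named with the results, the counts of Rpph1 (73.0% of its exon bases), Spp1 (18.8%), Smtn (16.3%), Rspo3 (13.1%) and Tlcd1 (10.1%) are uncertain for this reason. The group of each library and its replicate number came from the labels.

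Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 14483. Libraries were scaled by TMM, with factors from 0.951 to 1.03. The quasi-likelihood F-test with group as the only term gave p-values, adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The common biological coefficient of variation was 4.73% with 27.3 prior degrees of freedom. CPM values use the TMM-scaled library sizes, and log2 fold changes are Cre over GFP. Library totals lay between 12371994 and 14315903 counts, and the floor of 3 counts covers counting error only, since reads carry no molecular identifiers. The replicates of a group differed by more than counting noise. Among genes with over 200 counts the median chi-square was 2.26 times that of counting noise between the GFP libraries. It was 1.76 times between the Cre libraries, and from 3.10 to 4.59 times between libraries of different groups. The mean chi-square per gene, which few genes can dominate, ranked the pairs otherwise. It was 55.8 between the GFP libraries and 2.61 between the Cre libraries. Against Cre replicates 1 and 2 it was 12.2 and 16.4 for GFP replicate 1, and 84.6 and 92.1 for GFP replicate 2.

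Of 33 gene lists with 662 entries written before the data were examined, 28 had at least 5 tested genes and were tested on log2 CPM with a prior count of 2. Camera from limma 3.58.1, which compares a list with all other genes, was used with a preset inter-gene correlation of 0.01, and beside it camera with an estimated correlation and fry. P-values were adjusted over the 28 lists. Of these, 8 passed camera with the preset correlation. With the estimated correlation 0 passed, and 1, mitosis and G2/M, had an unadjusted p under 0.05. Fry called 5 lists on balance one way and 21 for change in either direction. Older symbols were matched through the NCBI gene number or RefSeq synonyms, and 2 entries were not found.

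Genes were named by a rule fixed before the data were examined. It took Setd2, the 12 largest rises and falls and the 10 smallest adjusted p-values per direction among called genes with an established symbol, a mean of at least 5 CPM and groups that do not overlap. It added up to 4 called members of each list at a mean of at least 1 CPM, and 12 genes of stromal cell fate and endotoxin binding. Further members named to complete a short count (Gas6, Cxcl12, Mcam, Ebf3, Cnn1, Adamts2, Adamts5, Sfrp1, Dkk3, Tgfbr2, Tgfb3 and Emr1) were chosen after their values were seen. Positions are those of RefSeq on GRCm38.p6, in which 31231 genes matched by NCBI gene number, 7757 by symbol and 5800 not at all. Transcript length and GC content came from the longest GENCODE M21 transcript, found for 33941 genes.

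On simulated counts for 14305 genes of this comparison, with 50 genes changed at each size, the test recovered 48% of genes changed 1.25-fold, 64% at 1.5-fold, 84% at 2-fold and 96% at 3-fold, and 8 of its 154 calls were unchanged genes. Camera with the preset correlation gave p under 0.05 for 2.8% of 1000 random lists. Genes were drawn independently in this simulation, without correlation between genes and without trends in GC content and length. Its rates therefore do not cover errors from these sources in the real libraries.

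The counts of called genes were recomputed with median-of-ratios size factors, scaling by library size alone, DESeq2 1.42.0, limma-voom, no low-count filter, a minimum of 1 CPM in 2 libraries, the replicate number as a block, robust dispersion estimates, an adjusted p of 0.01, and without each library in turn. Single genes were recomputed with all of these but the adjusted p of 0.01, and gene lists with all but that, DESeq2 and robust dispersion. A lone library left in a group is then assumed to vary like the other group. Alternatives chosen after the data were seen were a test on messenger RNA genes without Lars2 and an offset per library that removes smooth trends in GC content and transcript length (mgcv 1.9.3), and for 1 list the removal of Setd2. Gene families and neighbouring genes were recomputed only with the offset. The lentivirus sequences and the deletion within Setd2 were not analysed here.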

Results

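Gene expression was measured by RNA sequencing in bone marrow stromal cells from mice whose Setd2 gene carried loxP sites (Setd2 fl/fl, strain C57BL/6J). Setd2 encodes the histone methyltransferase that places the third methyl group on lysine 36 of histone H3, a mark of transcribed gene bodies. Cells at passage 2 received a lentivirus that carried either GFP, as the control, or Cre recombinase, which removes the floxed part of the gene, and were kept under puromycin at 2 µg/ml for 4 days. Each virus had 2 libraries. The GFP libraries held 12806928 and 12371994 counts and the Cre libraries 14311924 and 14315903 counts. Between 21190 and 21717 genes had at least 1 count per library. A count of 3, taken as the floor, corresponded to between 0.207 and 0.255 CPM, the read count normalized to library size. The labels do not say whether the libraries of a group came from separate cultures or animals, so each p-value measures only the spread between these libraries, which may be technical.

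Setd2 itself fell in the Cre libraries. This gene lies on chromosome 9 from 110532500 to 110618633 (GRCm38). It had 1400 and 1250 counts in the GFP libraries and 551 and 468 counts in the Cre libraries. In normalized units it went from 106 ± 0.0742 CPM with GFP to 35.2 ± 4.09 CPM with Cre (mean ± SD, n = 2 each), a log2 fold change of -1.60 with a standard error of 0.08 (adjusted p = 3.65e-15). All 4 libraries therefore carried Setd2 levels that match their labels. A gene total also counts reads from exons outside the floxed part, so the remaining counts do not measure intact transcript. Without GFP replicate 2 the log2 fold change was -1.59 with an adjusted p of 0.124.

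The comparison of Cre with GFP asks which genes change with deletion of Setd2 in stromal cells. This bone marrow population gives rise to osteoblasts and adipocytes. With GFP as the only control, the design does not separate loss of Setd2 from Cre itself for the genes and lists that follow. The neuropeptide precursor gene Vgf and the imprinted long noncoding RNA H19 rose, the BMP antagonist Grem1 and the metalloproteinase inhibitor Timp3 fell, and 17 of 27 mitosis genes and 10 of 26 interferon-induced genes fell. Most changes were small: the median absolute log2 fold change of the genes past the test was 0.36. Of 14483 genes tested, 1009 (6.97%) passed an adjusted p of 0.05, with 542 higher and 467 lower in Cre, and 70 of them differed at least 2-fold (30 higher, 40 lower). In 1007 of the 1009 genes both Cre libraries lay on the same side of both GFP libraries, which passing the test nearly requires. Over all tested genes this held for 50.04%, where chance gives 33.3%. Trends shared by many genes of a library can shift this share without an effect of the group. With scaling by library size alone 347 genes were higher and 183 lower. DESeq2 gave an adjusted p for 9827 genes, with a gene lacking one counted as not called, and called 380, 250 higher and 130 lower. Without a low-count filter edgeR called 30. The number of calls depended on single libraries: edgeR called 12 genes without GFP replicate 1, 516 without Cre replicate 1 and 373 without Cre replicate 2. Without GFP replicate 2 it called 0 genes, with 2197 genes at an unadjusted p under 0.05, and 1008 of the 1009 genes kept the sign of their fold change. This loss applies to every gene named as risen or fallen in the paragraphs that follow. The kept signs are no separate support. Where the groups did not overlap, leaving out a library could hardly reverse the sign.

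Vgf showed the largest rise among the genes named by the rule, from 6.08 ± 0.312 to 55.5 ± 2.69 CPM, a 9.14-fold difference (log2 fold change 3.19, standard error 0.11, adjusted p = 4.74e-19). It lies on chromosome 5 from 137025301 to 137033351. Rgs4, a regulator of G-protein signalling, rose from 30.5 ± 0.882 to 80.9 ± 1.73 CPM. H19, on chromosome 7 from 142575530 to 142578146, rose from 40.1 ± 1.48 to 84.3 ± 4.92 CPM (log2 fold change 1.07, standard error 0.08). Nnat, another imprinted gene, rose from 11.6 ± 0.411 to 23.1 ± 2.32 CPM. Further rises were those of Nxph3 (1.52 on the log2 scale), Isyna1 (1.20), which encodes inositol-3-phosphate synthase, Fut11 (1.16), Usp11 (1.10), Tlcd1 (1.05) and Vsig10l (0.93). Fut11, Usp11 and Isyna1 each lie within 5 kb downstream of a more abundant gene on the same strand. These neighbours, Sec24c, Cdk16 and Ell, had 181, 127 and 35.7 CPM over the 4 libraries. Whether reads running on from them add to the counts was not tested. Among the smallest p-values were also those of Hspb1, a small heat shock protein gene (0.76), and Ccdc85b (0.84). The count of Hcfc1r1 (1.52) is uncertain because 30.0% of its exon bases lie over exons of Thoc6 on the opposite strand, and that of Ccdc85b because 24.7% lie over Fosl1. The count of Myl12b (1.14) is uncertain too, since 38.5% of its exon bases are shared with its near-identical neighbour Myl12a, which had 763 CPM.

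Lars2 and noncoding RNAs aside, the largest falls by the naming rule were those of Avil, the gene of the actin-binding protein advillin, from 8.76 ± 0.979 to 2.52 ± 0.442 CPM (log2 fold change -1.79, standard error 0.19, adjusted p = 1.39e-07), of Setd2, and of the coagulation factor gene F5 (-1.18). These were followed by Clec4e (-0.96), a receptor gene of myeloid cells, and Grem1 (-0.94), on chromosome 2 from 113748675 to 113758648, which went from 69.2 ± 1.27 to 36.1 ± 4.00 CPM. Abundant genes with small p-values were the proteoglycan gene Vcan (755 ± 0.670 to 448 ± 28.5 CPM), Ptx3 (-0.80), the transcription factor gene Sox4 (-0.70) and Svep1 (-0.60). The nuclear long noncoding RNAs Malat1 (-0.82) and Neat1 (-0.68) fell as well. The counts of Sox4 and Svep1 are uncertain where antisense genes lie over 54.6% and 13.9% of their exon bases.

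**Figure D1:**
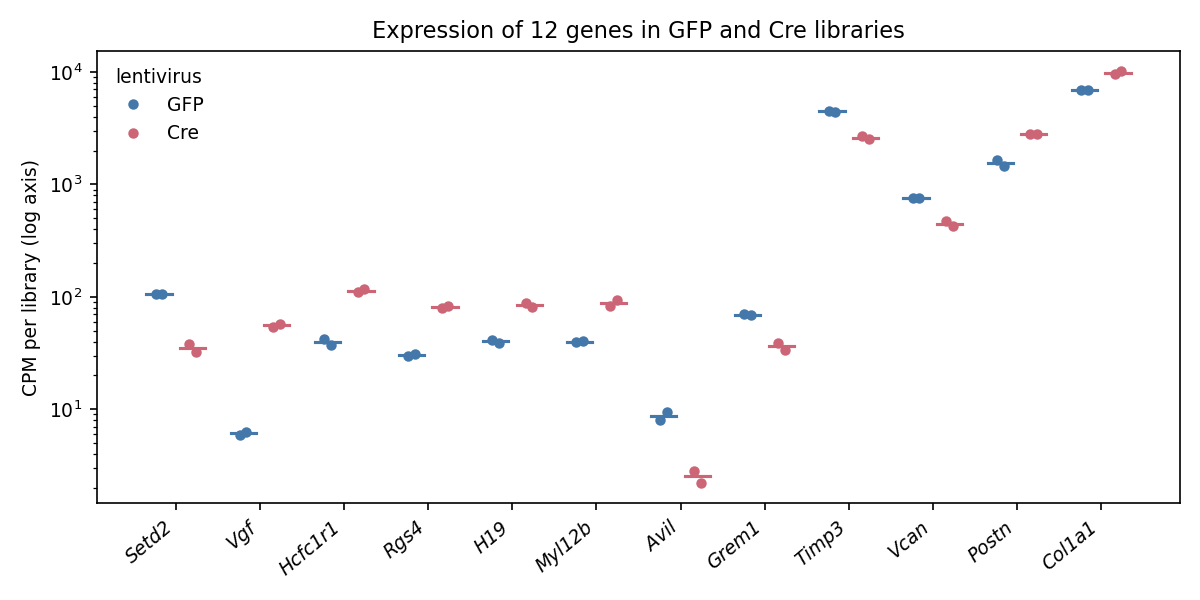
Expression in CPM on a log axis, with each point a library (blue GFP, red Cre) and each bar the mean of the 2 libraries of a group, for 12 of the named genes. Setd2 lay at 106 CPM on average with GFP and 35.2 CPM with Cre, and Vgf at 6.08 and 55.5 CPM.

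Ribosomal and other abundant noncoding RNAs stood apart in a single control library. The 18S ribosomal RNA gene Rn18s-rs5 took 7.45% of the counts of GFP replicate 2, against 2.07% in GFP replicate 1 and 1.35% and 1.21% in the Cre libraries. Of 9 such genes, Rn18s-rs5 (-1.96), Lars2 (-1.81), Rpph1 (-1.76) and Mir6236 (-1.65), with the mitochondrial ribosomal RNAs Rnr1 (-1.12) and Rnr2 (-1.02), were among the 12 largest falls. Lars2 encodes a mitochondrial leucyl-tRNA synthetase, but its count moved with the noncoding RNAs and was 4.26 times as high in GFP replicate 2 as in GFP replicate 1. Each of the 9 genes had to pass in the test on all libraries to enter the set, which favours a smaller value once a library is left out. Their median log2 fold change was -1.81 in all libraries and -0.42 without GFP replicate 2. Without that library the values were -0.67 for Rn18s-rs5 (adjusted p = 0.186), -0.41 for Lars2, -0.35 for Rpph1, -0.43 for Mir6236, -0.33 for Rnr1 and -0.21 for Rnr2, and without GFP replicate 1 Rnr2 stood at -1.54. With robust dispersion estimates none of these 6 genes passed (adjusted p = 0.438 for Rn18s-rs5). Tested on messenger RNA genes alone, without Lars2, an alternative chosen after the data were seen, 1146 genes passed.

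For cell fate, several genes of bone matrix rose, while of the regulators of either fate Sp7 rose and Runx2, Pparg and Cebpa did not pass. Col1a1, the gene of the main collagen chain of bone, went from 6896 ± 20.6 to 9901 ± 367 CPM (log2 fold change 0.52, standard error 0.06, adjusted p = 1.39e-07). Sp7, the osteoblast transcription factor osterix, rose from 14.6 ± 3.28 to 21.1 ± 1.64 CPM, and Ibsp, a bone sialoprotein gene, by 1.10 on the log2 scale, while the osteomodulin gene Omd fell (-1.21). Runx2, the master regulator of osteoblasts, had 59.2 ± 1.38 CPM with GFP and 60.4 ± 2.26 CPM with Cre (log2 fold change 0.03, adjusted p = 0.877). Values for Alpl were 0.05 (adjusted p = 0.789) and for Spp1 -0.10 (adjusted p = 0.391). Of the 14 osteoblast genes tested, 6 rose and 1 fell (7 and 1 when adjusted over the list alone), with a median of 0.27, and DESeq2 called 3 rises and 0 falls. The list passed camera (adjusted p = 0.00896) but not with an estimated correlation (adjusted p = 0.505 with an estimated correlation), nor in fry (adjusted p = 0.0761), nor without GFP replicate 2 (adjusted p = 0.0592). Sp7 had a log2 fold change of 0.32 without GFP replicate 2 and an adjusted p of 0.122 in DESeq2. The osteocalcin gene Bglap, with 2 and 1 counts in GFP and 2 and 2 in Cre, was too low to test.

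Adipocyte genes showed no common direction. Plin2, which coats lipid droplets, rose by 0.25 and the lipase gene Lpl by 0.24 on the log2 scale. They were the 2 of 20 tested genes that passed, none fell, and the median was -0.03 (camera adjusted p = 0.719). There were 4 rises and 1 fall when adjusted over the list alone. Pparg, the master regulator of adipocytes, stood at -0.13 (adjusted p = 0.453), Cebpa at 0.04 (adjusted p = 0.829) and Fabp4 at 0.36 (adjusted p = 0.0624). Adipoq had 0 and 0 counts in GFP and 2 and 1 in Cre, below the count filter. Lpl was at 0.14 without GFP replicate 2, and neither DESeq2 (adjusted p = 0.0945) nor scaling by library size alone (adjusted p = 0.0958) called it. Among 7 chondrocyte genes, the cartilage collagens Col11a1 (-0.39) and Col2a1 (-0.31) fell and none rose (camera adjusted p = 0.326), and 4 fell when adjusted over the list alone.

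Markers and niche factors of stromal progenitors went both ways. The surface antigen genes Thy1 (0.61) and Ly6a (0.52) and Gas6 (0.24) rose, while Grem1 (-0.94), the niche factor genes Kitl (-0.53) and Cxcl12 (-0.28), Ebf3 (-0.33) and Mcam (-0.26) fell. These 3 rises and 5 falls were among 21 genes tested, with 3 rises and 6 falls when adjusted over the list alone (camera adjusted p = 0.146). DESeq2 called 2 rises and 3 falls, and scaling by library size alone turned the balance, with 2 rises and 1 fall. Of 13 genes of myofibroblasts and smooth muscle, Myh11 (0.61), Smtn (0.35) and Cnn1 (0.22) rose and Tagln (-0.32) and Actg2 (-0.29) fell. Their number was 5 rises and 3 falls when adjusted over the list alone and in DESeq2, and 2 rises and 0 falls with scaling by library size alone (camera adjusted p = 0.680). Exons of an antisense gene lay over 62.4% of the exon bases of Tagln, whose count is uncertain.

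Several matrix genes rose. Postn, the gene of the matrix protein periostin, rose from 1564 ± 137 to 2821 ± 10.8 CPM (log2 fold change 0.85, standard error 0.06, adjusted p = 1.54e-10), and the collagen genes Col6a3 (0.48) and Col3a1 (0.33) rose. Of 26 collagen, elastic fibre and matrix genes, 7 rose and 1, Col11a1, fell, and adjusted over the list alone 7 rose and 5 fell. The list had a median of 0.08 and did not pass camera (adjusted p = 0.146). Fry, which asks whether genes move on balance one way, gave an adjusted p of 0.0340, against camera's adjusted p = 0.583 with an estimated correlation. Among 17 metalloproteinases and their inhibitors, Timp3 fell from 4472 ± 98.0 to 2610 ± 107 CPM (log2 fold change -0.78) and Mmp9 (-0.46) and Adamts5 (-0.33) fell. The macrophage elastase gene Mmp12 rose from 104 ± 3.68 to 178 ± 2.51 CPM, and Mmp23 (0.51) and Adamts2 (0.24) rose. Adjusted over the list alone, 5 rose and 3 fell (camera adjusted p = 0.237; adjusted p = 0.602 with an estimated correlation; fry adjusted p = 0.0340). Mmp9 was at -0.14 without GFP replicate 2 and at -0.73 without GFP replicate 1. Exons of the antisense gene Syn3, at 2.22 CPM, lay over 21.3% of the exon bases of Timp3.

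Mitosis genes had the smallest camera p-value of the gene lists. Of 27 mitosis and G2/M genes tested, 17 fell and none rose, and 0 of the 27 had a log2 fold change above 0. The centromere protein gene Cenpf went from 35.1 ± 0.341 to 21.9 ± 2.22 CPM (log2 fold change -0.68, standard error 0.09, adjusted p = 8.70e-06). Hmmr (-0.48), the spindle motor gene Kif11 (-0.46) and the checkpoint kinase gene Bub1 (-0.44) fell too. The median was -0.31, 23 genes fell when adjusted over the list alone, DESeq2 called 6 falls, and scaling by library size alone gave 7. Camera gave an adjusted p of 5.66e-12 and fry one of 0.0340, but the camera call was lost with an estimated correlation (adjusted p = 0.505 with an estimated correlation, unadjusted p = 0.0272). Of 27 genes of DNA replication 1, the polymerase gene Pole (-0.40), fell, also when adjusted over the list alone. Their median was -0.12 (camera adjusted p = 0.00644; adjusted p = 0.583 with an estimated correlation; fry adjusted p = 0.130), and camera gave an adjusted p of 0.0988 without GFP replicate 2. Of 14 genes of senescence and cell cycle arrest, only the lysosomal galactosidase gene Glb1 rose (0.25), with 2 rises when adjusted over the list alone (camera adjusted p = 0.326). Among 24 p53 targets, Pmaip1 (0.26) and Plk2 (0.23) rose and Eda2r (-0.30) fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.836). DESeq2 and scaling by library size alone each called 0 of the 24.

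Of 26 genes induced by type I interferon, 10 fell and none rose. Ifit1 went from 28.8 ± 1.41 to 15.4 ± 1.29 CPM (log2 fold change -0.90, standard error 0.10, adjusted p = 4.01e-07), and the nucleic acid sensor gene Zbp1 (-0.92), Cmpk2 (-0.87) and Ifit3 (-0.74) fell. There were 14 falls when adjusted over the list alone, DESeq2 called 2 falls, scaling by library size alone gave 5, and the median was -0.29. The list passed camera (adjusted p = 1.82e-05) but not with an estimated correlation (adjusted p = 0.505 with an estimated correlation) and not in fry (adjusted p = 0.0666). Of 11 genes of endotoxin sensing and the acute phase, Lcn2 (-0.97), the complement gene C3 (-0.57), the serum amyloid gene Saa3 (-0.47) and Hp (-0.44) fell and none rose. Adjusted over the list alone, 1 rose and 4 fell, DESeq2 called 1 fall and scaling by library size alone gave 3. Lbp, the gene of lipopolysaccharide-binding protein, had 10 and 6 counts in GFP and 5 and 6 in Cre, below the count filter. Camera gave this list an adjusted p of 0.138 in all libraries (adjusted p = 0.602 with an estimated correlation) and 0.0445 without GFP replicate 2. Among 19 cytokine and chemokine genes of the NF-kappaB response, Ptgs2 rose (0.21) and Lif fell (-0.23), with 3 rises and 4 falls when adjusted over the list alone (camera adjusted p = 0.237).

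Some Wnt pathway genes fell, while most did not pass. The receptor genes Fzd1 (-0.50) and Fzd8 (-0.41), the Wnt agonist gene Rspo3 (-0.86) and the transcription factor gene Tcf7l2 (-0.36) fell, and so did the genes of the secreted Wnt-binding protein Sfrp1 (-0.32) and of Dkk3 (-0.27). They made 6 falls and 0 rises among 28 genes tested, DESeq2 called 3 falls, and adjusted over the list alone 1 rose and 7 fell. The median was -0.14 (camera adjusted p = 0.0201; adjusted p = 0.505 with an estimated correlation; fry adjusted p = 0.0355). Camera gave an adjusted p of 0.0811 without GFP replicate 1 and 0.0774 without Cre replicate 1, and Rspo3 was at -0.54 without GFP replicate 2. Of 28 genes of the BMP and TGF-beta pathways, 6 rose, among them Tgfbi (0.46) and Tgfb2 (0.39), and 4 fell: Grem1, the coreceptor gene Tgfbr3 (-0.61), Tgfbr2 (-0.21) and Tgfb3 (-0.20). Adjusted over the list alone, 8 rose and 6 fell (camera adjusted p = 0.724).

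Among 24 genes that write, read or erase methylation of histone H3 lysine 36, Setd2 fell most. The other 3 that fell were the mismatch repair gene Msh6 (-0.37), whose protein binds the trimethyl mark, and the dimethyltransferase genes Whsc1 (-0.29) and Nsd1 (-0.27). None rose, and 6 fell when adjusted over the list alone. Camera gave an adjusted p of 0.138 in all libraries (adjusted p = 0.743 with an estimated correlation) and 0.0357 without Cre replicate 1, but part of this is the deleted gene itself: on the other 23 genes, a test chosen after the results were seen, the values were 0.237 and 0.0961. Nsd1 stood at -0.16 without GFP replicate 2, and DESeq2 called none of Msh6, Whsc1 and Nsd1.

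Of 24 genes of glycolysis and hypoxia, 10 rose and 1 fell. P4ha2, a collagen prolyl hydroxylase gene, went from 229 ± 4.71 to 317 ± 11.1 CPM (log2 fold change 0.47, standard error 0.06, adjusted p = 9.91e-06), and Egln3 (0.43) and the phosphofructokinase gene Pfkp (0.33) rose. The phosphoglycerate kinase gene Pgk1 was the exception, with a fall from 128 ± 10.2 to 87.7 ± 4.86 CPM. Of these, 13 rose and 1 fell when adjusted over the list alone, and the median was 0.19. The list passed camera (adjusted p = 2.65e-04) but not with an estimated correlation (adjusted p = 0.505 with an estimated correlation) and not in fry (adjusted p = 0.0761). Of 26 nuclear genes of the respiratory chain, Uqcrc1 rose (0.22) and none fell, with 0 past edgeR's test when adjusted over the list alone, 0 in DESeq2 and 1 in limma-voom, where 4 had an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.138). Of 13 genes of the mitochondrial genome, the ribosomal RNAs Rnr1 and Rnr2 fell, also when adjusted over the list alone. Without GFP replicate 2, in which their levels were 2.46 and 2.51 times those of GFP replicate 1, they stood at -0.33 and -0.21 and did not pass. Camera gave this list an adjusted p of 0.138 (adjusted p = 0.685 with an estimated correlation), and 0.0357 without Cre replicate 1. Of 30 ribosomal protein genes, 27 had a log2 fold change above 0, but 1, Rplp1 (0.25), rose, also when adjusted over the list alone. Their median was 0.09 (camera adjusted p = 0.00532; adjusted p = 0.685 with an estimated correlation; fry adjusted p = 0.274), and camera gave adjusted p-values of 0.108 without GFP replicate 2, 0.145 without Cre replicate 2 and 0.0992 with the GC and length offset, an alternative chosen after the results were seen. These genes have many processed pseudogenes, so their counts are uncertain.

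In the unfolded protein and amino acid response, Trib3 (-0.42), the cystine transporter gene Slc7a11 (-0.39) and Ddit3 (-0.32) fell among 20 genes, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.719). Trib3 stood at -0.21 without Cre replicate 1 and -0.65 without Cre replicate 2. Of 16 NRF2 targets, Gstm1 (0.37) and G6pdx (0.32) rose and Slc7a11 fell, with 3 rises and 1 fall when adjusted over the list alone (camera adjusted p = 0.326). The count of G6pdx is uncertain, since exons of Ikbkg, at 118 CPM, lie over 13.6% of its exon bases on the opposite strand. Of 19 cholesterol synthesis genes 0 passed in edgeR, DESeq2 and limma-voom and when adjusted over the list alone, with 3 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.980). Of 21 immediate early genes, Jun (0.32) and Ier3 (0.26) rose and Nr4a1 (-0.36) and Fosl2 (-0.22) fell, with 3 rises and 2 falls when adjusted over the list alone (camera adjusted p = 0.719). DESeq2 and scaling by library size alone each gave 1 rise and 0 falls. Fosl2 was at -0.14 without GFP replicate 2.

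Markers of macrophages were present in all 4 libraries, and 6 of 20 rose with Cre. The macrophage lysozyme gene Lyz2, at 1545 CPM over the 4 libraries, was the most abundant of the macrophage and monocyte genes. Mrc1 rose from 32.1 ± 1.14 to 42.9 ± 4.20 CPM (log2 fold change 0.42, standard error 0.09, adjusted p = 0.00233), and Trem2 (0.35), the complement gene C1qb (0.31) and Cd68 (0.30) rose. Of the 20 genes 1, Emr1, which encodes the surface marker F4/80, fell (-0.30). DESeq2 called 3 rises and 1 fall, and adjusted over the list alone 8 rose and 1 fell. The median was 0.17 (camera adjusted p = 0.00141; adjusted p = 0.505 with an estimated correlation; fry adjusted p = 0.0632). Of 6 osteoclast genes, Acp5 (-0.45) and Mmp9 (-0.46) fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.180; adjusted p = 0.602 with an estimated correlation; fry adjusted p = 0.0340). DESeq2 called 0 falls in this list and scaling by library size alone gave 1. Mmp9 was at -0.14 without GFP replicate 2. Of 8 endothelial genes 0 passed in edgeR, DESeq2 and limma-voom and when adjusted over the list alone, with 1 at an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.326). Few genes of other types could be tested. Among them 4 of granulocytes, 1 of lymphocytes and 1 of erythroid cells gave 0 calls in edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05, the neural gene Tubb3 (0.40) rose and Ncam1 (-0.33) fell, and the muscle actin gene Acta1 rose (0.60), with the same counts when adjusted over the list alone.

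**Figure D2:**
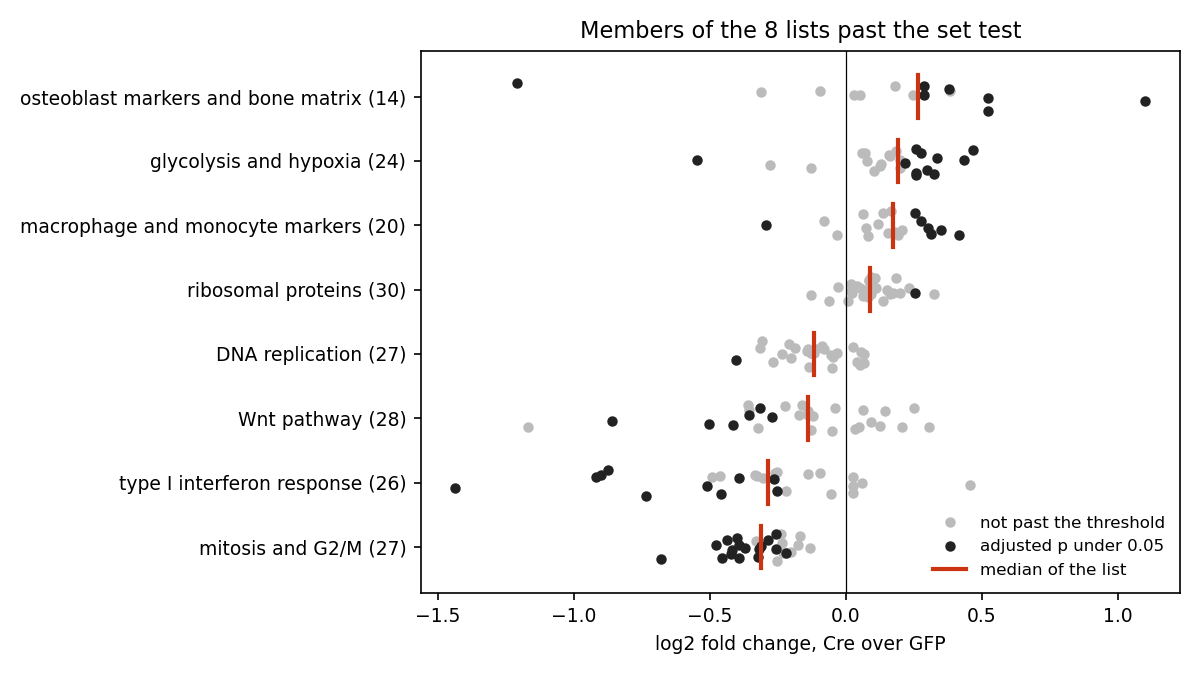
Log2 fold change of Cre over GFP for each tested member of the 8 gene lists past camera with a preset correlation, with the number of tested genes in parentheses. Black points passed an adjusted p of 0.05 over all genes, grey points did not, and red bars mark medians, from -0.31 for mitosis and G2/M to 0.27 for osteoblast markers; with an estimated correlation 0 lists passed.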

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

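The alternatives on messenger RNA genes alone, with a GC and length offset and without Setd2 in its list were chosen only after the results were seen. Against 1009 calls, library size alone gave 530, DESeq2 380, no low-count filter 30 and an adjusted p of 0.01 gave 477; leaving out a library gave from 0 to 516. For the 70 calls of at least 2-fold, DESeq2 gave 9, no filter 9, and leaving out a library from 0 to 70. Beyond the fewer samples of the last, the cause was not tested. Without GFP replicate 1 or 2 the prior degrees of freedom were 3.70 and 3.41, against 27.3 with all libraries. They were 38.2 without Cre replicate 1 and infinite without Cre replicate 2. The common biological coefficient of variation was 3.44% without either GFP library, against 4.73% with all libraries. It was 5.67% without Cre replicate 1 and 5.62% without Cre replicate 2. The low prior degrees of freedom thus went with leaving out either GFP library, not GFP replicate 2 alone. Setd2 ranged from -1.71 to -1.48 when a library was left out and passed in all but the fit without GFP replicate 2. Against 8 gene lists, camera with an estimated correlation called 0 and fry 5; the cause was not tested. No named gene that passed reversed in any alternative. This is little support, since in 1007 of the 1009 called genes the groups did not overlap, which made reversal unlikely from the start. Of 105 named genes that passed, all passed with median-of-ratios factors, limma-voom and the 1 CPM minimum, 104 with the GC and length offset, 99 with robust dispersion, 80 with library size alone, 18 without a filter, and 58 of 93 in DESeq2. Median-of-ratios factors gave 1012 calls, limma-voom 1042, the 1 CPM minimum 1159, robust dispersion 1334, and the GC and length offset 1420. The fit with the replicate block gave 829 calls, 825 of them shared with the 1009, changed no list's call and lost 7 named genes. The replicate numbers pair nothing in the labels, and the deviations of same-numbered libraries had a correlation of -0.009. In simulation at this depth with 2 libraries per group, 48% of the smallest changes were recovered.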

Other observations

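Tests of the GC trend within groups, of the matrix list against the mitosis list, of imprinted genes and of gene families were chosen only after the result was seen, as were the GC and length offset and the control classes of neighbouring genes, which were added after the unadjusted odds ratio.

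Among 147 families of genes that share a symbol stem, 4 passed camera, and none did with an estimated correlation (adjusted p = 0.983 for each of the 4). Of 14 tested genes of the Pcdhb cluster, which encode neural cell adhesion molecules, 2 fell and none rose, with a median log2 fold change of -0.35 (camera adjusted p = 0.00129 over the families). The others were the stems Rps (45 genes, median 0.09, adjusted p = 0.0145), Rpl (47 genes, median 0.09, adjusted p = 0.0321) and Cep (31 genes, median -0.12, adjusted p = 0.0309). Rps and Rpl are the stems of ribosomal protein genes and Cep that of centrosomal genes. A stem takes in every gene whose symbol starts alike, so these sets need not hold such genes alone. The 12 genes of the Pcdhga cluster, next to Pcdhb, and the 12 chemokine genes of the Ccl family did not pass, with medians of 0.11 and 0.22 (adjusted p = 0.0915 for both). With the GC and length offset Pcdhb passed (median -0.32, adjusted p = 0.00914), while Rps (0.06, adjusted p = 0.0836), Rpl (0.05, adjusted p = 0.320) and Cep (-0.06, adjusted p = 0.115) did not. Besides H19 and Nnat, the 35 imprinted genes tested did not rise as a set, with a median of 0.0102, 1 rise (Asb4) and 2 falls (Mest and Kcnq1ot1). Genes expressed from the maternal and the paternal copy were pooled, so opposite shifts of these kinds were not tested.

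Genes that rose had a median transcript length of 2682 bp and 55.2% GC, genes that fell 4761 bp and 46.6%, and genes not called 3248 bp and 49.6%. Over 13366 genes, which are not independent replicates, the fold change ran with GC content (Spearman rho 0.31) and against length (rho -0.23). The values argue against smooth GC or length bias between libraries as the whole cause of the calls. With the GC and length offset, 89.4% of the calls passed in the same direction. The offset also raised the number of calls from 1009 to 1420, which can by itself raise this share. It removes no other difference between libraries, such as the share of ribosomal RNA, so bias of other kinds was not tested by it. GC or length bias stays a candidate explanation for the trend itself, because replicates of a group differed along it too. The Cre libraries differed from each other with a rho of 0.222 with GC content and -0.23 with length. For the GFP libraries these values were 0.19 and 0.21. An effect of Setd2 loss on long genes remains open and was not tested.

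Whether a larger share of macrophages, a change of cell composition, lowered the level of mitosis genes stays open. The values argue against GC or length bias, a technical explanation, as the whole cause of the lower level of mitosis genes. With the GC and length offset the median of the list was -0.30 (camera adjusted p = 1.10e-12), against -0.31 without it, where camera gave an adjusted p = 0.505 with an estimated correlation. A larger share of macrophages, of whose 20 tested markers 6 rose and 1 fell, would dilute stromal matrix genes as well. The median of the matrix list lay 0.40 above that of the mitosis list (95% range of resampled medians 0.23 to 0.51), so matrix genes did not fall alike. This range resamples genes, not libraries. Rises of matrix genes, of which 7 passed, could also hide a dilution, so the comparison does not settle the share of macrophages. Whether the Cre-treated cells divided less was not measured, and the design, with GFP as the only control, does not separate loss of Setd2 from Cre itself.

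Genes with an expressed gene (at least 1 CPM) ending within 5 kb upstream on the same strand rose more often: 99 of 1471 (6.73%) against 436 of 12450 others (3.50%), an odds ratio of 1.99 (95% interval 1.57 to 2.50, Fisher's exact test, two-sided, adjusted p = 9.23e-08 over 4 neighbour classes). Genes are not independent replicates, so this p-value and the intervals given here measure no spread between libraries. With GC content, length, expression and the other neighbour classes together in the model, terms that were not separated, the odds ratio was 1.35 (1.06 to 1.72). This argues only weakly against short, GC-rich genes in dense regions as the whole cause, since the lower limit lies near 1. Falls in these classes were not tested, so an excess of calls in both directions stays open. Genes whose neighbour is transcribed away from them had an adjusted odds ratio of 0.70 (0.51 to 0.96), so that the ratio of both, 1.93 (1.32 to 2.84), rests in part on this class lying below 1, and the adjusted odds ratio was 0.77 (0.58 to 1.02; 0.67, 0.52 to 0.87, with the offset) for a downstream neighbour on the same strand and 0.99 (0.78 to 1.26; 0.97, 0.78 to 1.19, with the offset) for a convergent one. Whether transcription runs on past gene ends into the next gene without Setd2 stays open, because the kit keeps no strand and reads running on from a convergent neighbour would be counted too, but that class showed no excess in the model (1.42, 1.12 to 1.78, without it). Nor was it settled whether the rise scales with the neighbour's expression. The rho of the fold change with the neighbour's relative level was 0.02 (one-sided permutation p = 0.184). It was -0.08 in the control class, genes whose neighbour is transcribed away from them. The difference of 0.10 (permutation p = 0.0026) thus rests largely on the negative value of the control class.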
